A study of Homo sapiens with 6 samples.

How the data were processed

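RNA was measured in 6 libraries of AsPC-1, an established human pancreatic adenocarcinoma cell line. Per the labels, 3 libraries come from cells given vehicle and 3 from cells given 6-diazo-5-oxo-L-norleucine (DON) for 24 h in medium without serum. DON is a glutamine analog that inactivates enzymes which use glutamine. Poly(A) RNA was selected, strand-directed libraries were made and single 75 bp reads were sequenced, per the labels' protocols. The labels number the libraries of each group 1 to 3. The columns of the deposited table that carry the word control were taken as the vehicle libraries by their number. Nothing in the labels says how the replicates were separated, so p-values measure the spread between these samples, which may be technical.

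The authors deposited a table of FPKM values (fragments per kilobase of transcript scaled to the library's mapped fragments) with 1 row per gene symbol and 1 column per library. The reads were aligned with STAR to hg19, per the submitters' processing notes, which carry no versions. The program that computed FPKM, the annotation, the use of strand in counting and any scaling between libraries are not given in the sources used here. The table held 26228 rows. No value was exactly 0, the lowest value was 0.01, and 40.3% to 45.8% of rows per library stood at that floor. In 41 rows, 72 cells held a failure mark in place of a value, and these genes were left out of the tests. A spreadsheet had turned 28 symbols into dates, and 4 rows shared a symbol with another row. These genes cannot be named with certainty. The 13 mitochondrially encoded genes of the fixed lists were not analysed here. Of 1074 list entries, 1061 were found under a current or older symbol.

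FPKM values hold no read counts, so absolute depth is unknown and no counting interval is given. Steps between the lowest values (up to 0.3 FPKM) of the same gene give a rough relative depth. Against vehicle replicate 1, it was 1.70 for vehicle 2, 1.29 for vehicle 3, 1.39 for DON 1, 1.35 for DON 2 and 1.25 for DON 3. These ratios rest on 34 to 56 genes at the commonest ratio among 513 to 602 genes compared. Vehicle replicate 1 was thus the shallowest library, and it held 23 of the failure marks.

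Values were transformed to log2(FPKM + 1), so fold changes on that scale understate the change of genes near or below 1 FPKM. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, which left 11471. DON was compared with vehicle in limma 3.58.1 (R 4.3.3) with moderated variances and an intensity trend, without a robust option and without a replicate block. Tests were two-sided. Benjamini-Hochberg adjustment ran over all tested genes at a threshold of 0.05. Fold values beside FPKM means are ratios of those means, while log2 fold changes come from the fit. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

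A set of 42 gene lists covered polarity, macropinocytosis, growth factor receptors, amino acid and nucleotide metabolism, lipids, energy metabolism, stress responses, cell cycle, epithelial and tumour identity, inflammation, housekeeping classes and markers of other cell types. Some genes belong to several lists. The 36 lists with at least 5 tested members were tested against all other tested genes with limma's camera at its preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation was an alternative. Counts adjusted over a list alone re-adjust the same gene p-values within that list. In a list rich in called genes they tend to hold, so they are not separate evidence. Limma's fry was also run, which tests whether members of a list move one way on balance and does not compare them with other genes. The genes named in the text follow a rule. It took the 12 largest rises and the 12 largest falls among called genes with a mean of at least 5 FPKM in the higher group and no overlap between groups. Symbols of multigene families and of non-coding or uncharacterised genes were skipped by their prefixes in that part. It also took all Par complex members, up to 4 called members of every other list by size of change (where none was called, the tested member with the highest mean), and ASNS, DDIT3, TRIB3, ATF4, GFPT1, PPAT, CAD, EGFR, MKI67, CDKN1A and HSPA5. Some genes that the rule takes are not reported here. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except where the text says that a choice came after.

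The alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, limma without a trend, a replicate block and leaving out each library in turn. Chosen after seeing the data were a correction for GC content, a term for a split of the libraries seen in their principal components, a fit that kept genes with a failure mark, and a fit without 68 small RNA genes. The GC correction removed a natural spline with 4 degrees of freedom from each library, with GC content taken by symbol from the longest GENCODE 29 transcript, which gave a value for 95.0% of tested genes. That annotation belongs to another genome build than the deposited values, so no coordinates are given.

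The procedure was tested on simulated data with the tested genes' own vehicle means and a spread smoothed over the mean. Noise was independent between genes and libraries, and 50 genes were changed at each size. The gene and list tests held no library split and no GC trend, so their error rates need not hold for the real libraries. In a simulated comparison over 11471 genes, limma recovered 64% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1, 2 or 3. False calls made up 3.70% of all calls. In the simulated list test, a raised list passed (adjusted p = 3.2e-20) and 0 of the unchanged lists did. Genes with near-identical copies, among them HSPA1A and HSPA1B, ACOT1, the histones and ribosomal proteins, are uncertain because the counting of shared reads is not stated, and so are genes that overlap another gene.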

Results

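The transcriptome of AsPC-1 pancreatic cancer cells was compared between 3 vehicle libraries and 3 libraries from cells given the glutamine antagonist DON for 24 h. The series title names cell polarity proteins and macropinocytosis, the bulk uptake of extracellular fluid, in metabolic stress. The comparison asks which transcripts change when glutamine use is blocked. FPKM sums ranged from 525200 to 556950 per library, and 11292 to 11474 genes reached 1 FPKM. Pearson correlations of log2 values across genes were 0.966 to 0.977 within vehicle, 0.971 to 0.990 within DON and 0.923 to 0.949 between the groups. The first principal component separated the groups and held 61.6% of the variance. The second held 19.7%, and its scores were graded, from -0.616 in DON 1 to 0.624 in vehicle 3. Vehicle 1 stood at -0.302, vehicle 2 at -0.144, DON 2 at 0.111 and DON 3 at 0.327. The sign of the score parted vehicle 1, vehicle 2 and DON 1 from vehicle 3, DON 2 and DON 3, with no clear gap between them. Along that split the libraries also differed in GC content. Spearman correlations across genes between deviation and GC were 0.228, 0.303 and 0.505 in the former and -0.401, -0.417 and -0.410 in the latter. Deviations were taken from the mean of each group, so an outlying library tilts the others of its group the opposite way.

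Genes of the endoplasmic reticulum stress response and of the ATF4 amino acid response rose with DON, and genes of lipid synthesis and mitosis fell. ASNS, which makes asparagine from glutamine and aspartate, rose 8.51-fold from 36.4 ± 3.35 to 310 ± 31.8 FPKM (mean ± SD, n = 3 per group). HSPA5, the main chaperone of the endoplasmic reticulum, rose from 121 ± 15.1 to 770 ± 92.5 FPKM. FASN, the fatty acid synthase, fell 7.65-fold from 70.3 ± 13.2 to 9.19 ± 2.20 FPKM, and TOP2A, the DNA topoisomerase of dividing cells, fell 5.69-fold from 66.7 ± 2.61 to 11.7 ± 0.671 FPKM. In all, limma called 4459 of 11471 tested genes (38.9%), 2096 higher and 2363 lower in DON. At least 2-fold changes on the log2(FPKM + 1) scale were called for 802 genes, 325 higher and 477 lower. Without DON replicate 2 the number of called genes was 2688, with 1184 higher and 1504 lower, while 758 passed the 2-fold count.

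The largest rises under the naming rule, which ranks genes on the log2(FPKM + 1) scale, included BHLHA15, a transcription factor of secretory cells. It went from 1.56 ± 0.651 to 25.7 ± 6.43 FPKM (log2 fold change 3.39 ± 0.23 SE, limma adjusted p = 0.000114). ERO1B, an oxidase of disulfide bond formation, went from 0.211 ± 0.0593 to 10.4 ± 0.675 FPKM, by ratio of means a larger change (49.2-fold) than that of BHLHA15 (16.5-fold). The xenobiotic-metabolising enzyme CYP1A1 rose from 2.07 ± 0.188 to 27.0 ± 1.13 FPKM and the cadherin CDH15 from 0.310 ± 0.0632 to 10.5 ± 0.896 FPKM. NUCB2, a calcium-binding protein, rose 8.32-fold and MTHFD2, an enzyme of mitochondrial folate metabolism, rose 6.95-fold. CRELD2, SDF2L1, DNAJB9 and HERPUD1, all genes of endoplasmic reticulum stress, rose 9.13-fold, 7.65-fold, 7.46-fold and 6.78-fold. Among the largest falls, the growth factor receptor FGFR4 went from 69.4 ± 12.05 to 8.76 ± 2.55 FPKM and the FGF-binding protein FGFBP1 from 70.8 ± 2.51 to 9.90 ± 0.596 FPKM. The mitotic genes HMMR, KIF20A and FAM64A fell 5.96-fold, 8.07-fold and 9.53-fold. ACAT2 and DHCR7 of sterol synthesis fell 6.00-fold and 5.49-fold, and ACSL1, which activates fatty acids, fell 10.2-fold. ACOT1, whose near-identical copy ACOT2 makes its value uncertain, fell 6.16-fold. Adjusted p for the genes named here by size of change ranged from 1.61e-05 to 0.000824.

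**Figure D1:**
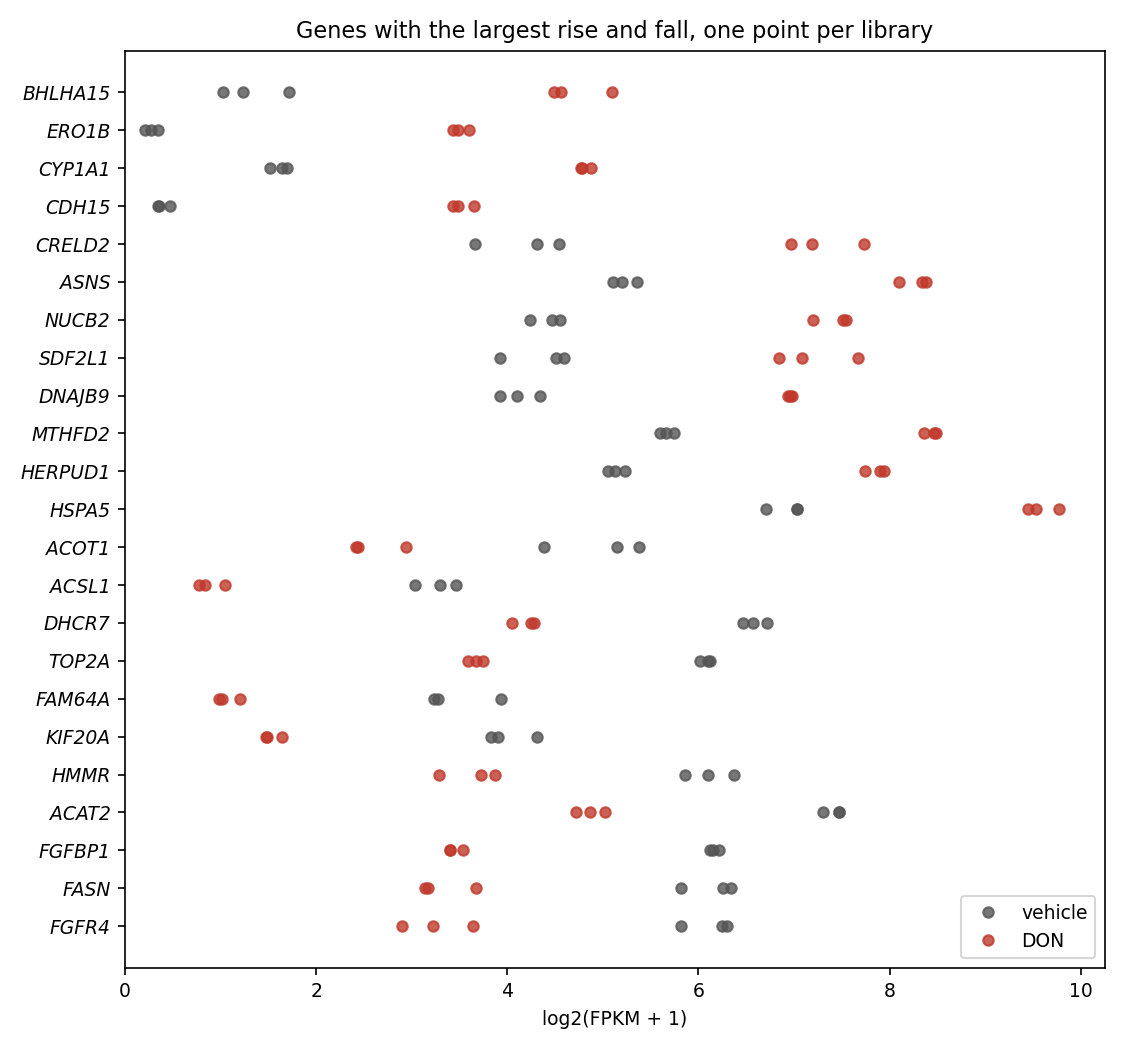
log2(FPKM + 1) of genes with the largest rises and falls under the naming rule, with 1 point per library (grey vehicle, red DON). The 3 libraries of each group do not overlap with those of the other for any gene shown, which the naming rule required.

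Of 36 gene lists tested with limma's camera at its preset correlation, 20 shifted, 10 upward and 10 downward. With an estimated correlation 6 held, each at adjusted p = 0.0433. These were the unfolded protein response, the ATF4 amino acid response and autophagy upward, and mitosis, cholesterol synthesis and S phase downward.

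The amino acid response driven by the transcription factor ATF4 rose as a group. Of 35 tested members 31 rose and 0 fell, and 31 rose when adjusted over the list alone (median log2 fold change 1.24, camera adjusted p = 4.5e-16). ATF4 itself went from 191 ± 11.4 to 381 ± 39.1 FPKM. Its targets DDIT3, a stress transcription factor, and TRIB3, a pseudokinase, rose 6.11-fold and 4.66-fold to 209 ± 26.5 and 206 ± 37.0 FPKM. Among amino acid transporters, 10 of 18 rose and 2 fell, with the same counts when adjusted over the list alone (median 0.54, adjusted p = 0.0029, and adjusted p = 0.084 with an estimated correlation). SLC3A2, the heavy chain shared by several transporters, rose from 114 ± 11.98 to 467 ± 84.5 FPKM and its partner SLC7A5 from 31.7 ± 2.77 to 67.0 ± 2.24 FPKM. SLC1A4 rose from 0.234 ± 0.0905 to 3.21 ± 0.137 FPKM and the glycine transporter SLC6A9 from 0.830 ± 0.183 to 4.90 ± 0.290 FPKM. The transporters named here also belong to the ATF4 list. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 14 rose and 1 fell, and 14 and 2 did when adjusted over the list alone (median 0.65, adjusted p = 9.9e-06, and adjusted p = 0.084 with an estimated correlation). WARS, GARS and SARS rose 3.32-fold, 2.34-fold and 2.11-fold, whereas VARS fell 2.31-fold.

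Genes of the unfolded protein response of the endoplasmic reticulum showed the highest median of all tested lists. Of 29 tested members 26 rose and 0 fell, and 27 rose when adjusted over the list alone (median log2 fold change 1.83, camera adjusted p = 2.9e-19). Per-library medians lay between 1.75 and 1.87 in DON and between -0.019 and 0.079 in vehicle. DNAJB9, a co-chaperone, went from 16.5 ± 2.53 to 123 ± 1.82 FPKM, and CRELD2 from 17.6 ± 5.39 to 161 ± 46.1 FPKM. Heat shock protein genes moved the opposite way, with 1 of 15 higher and 9 lower, also when adjusted over the list alone (median -0.57, adjusted p = 0.0056, and adjusted p = 0.092 with an estimated correlation). HSPB1 fell from 358 ± 22.4 to 164 ± 9.01 FPKM and HSP90AA1 from 473 ± 33.9 to 269 ± 17.1 FPKM. HSPA1A and HSPA1B fell 3.02-fold and 2.39-fold, but these near-identical copies share reads and their separate values are uncertain.

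Enzymes that use or make glutamine and glutamate went both ways. Of 23 tested, 5 rose and 9 fell, and 6 and 9 did when adjusted over the list alone (median -0.16, mean 0.0037, camera adjusted p = 0.893). GFPT1, the glutamine-using entry enzyme of the hexosamine pathway, rose from 21.7 ± 0.937 to 77.7 ± 0.434 FPKM. ALDH18A1, which starts proline synthesis from glutamate, fell from 123 ± 3.21 to 36.1 ± 2.59 FPKM, and PYCRL, which ends it, fell 3.55-fold. PPAT, the glutamine-using entry enzyme of purine synthesis, stood at 12.3 ± 0.686 FPKM in vehicle and 12.3 ± 0.163 FPKM in DON (log2 fold change 0.01, 95% interval -0.19 to 0.20, adjusted p = 0.953). CAD, which starts pyrimidine synthesis, stood at 17.8 ± 3.31 and 13.6 ± 3.17 FPKM (adjusted p = 0.163, and 0.0405 without DON replicate 1). In the wider hexosamine and glycosylation list 14 of 30 rose and 6 fell, and 16 and 6 did when adjusted over the list alone (median 0.32, adjusted p = 0.0066, and adjusted p = 0.089 with an estimated correlation). PGM3, the hexosamine pathway's mutase, rose from 8.38 ± 0.313 to 31.2 ± 2.46 FPKM, and STT3A, a catalytic subunit of oligosaccharyltransferase, rose 2.19-fold. MGEA5, which removes O-linked N-acetylglucosamine from proteins, fell from 36.9 ± 3.005 to 13.3 ± 0.738 FPKM.

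In nucleotide synthesis 0 of 30 tested genes rose and 15 fell, also when adjusted over the list alone (median -0.33, adjusted p = 0.00067, and adjusted p = 0.223 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, fell from 33.5 ± 1.68 to 9.49 ± 0.337 FPKM. The thymidine kinase TK1, the thymidylate synthase TYMS and the CTP synthase CTPS1 fell 2.74-fold, 2.80-fold and 1.99-fold. RRM2 and TYMS also belong to the S phase list, so the shifts of these lists are not separate findings. In serine, glycine and folate metabolism 4 of 16 rose and 3 fell, and 4 and 4 did when adjusted over the list alone (median -0.16, mean 0.066, adjusted p = 0.893). MTHFD2 rose from 49.8 ± 2.62 to 346 ± 16.1 FPKM and PSAT1, of serine synthesis, from 11.3 ± 1.02 to 33.1 ± 1.12 FPKM, while the cytosolic SHMT1 fell 2.39-fold.

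Genes of cholesterol and fatty acid synthesis fell. Of 24 tested cholesterol genes 0 rose and 23 fell, also when adjusted over the list alone (median log2 fold change -1.68, camera adjusted p = 7.8e-16). ACAT2 fell from 170 ± 11.3 to 28.3 ± 3.06 FPKM, DHCR7 from 95.01 ± 8.46 to 17.3 ± 1.57 FPKM and the sterol reductase TM7SF2 from 32.3 ± 0.381 to 6.21 ± 0.239 FPKM. Of 19 fatty acid synthesis genes 0 rose and 16 fell, and 18 fell when adjusted over the list alone (median -1.16, adjusted p = 4.3e-11, and adjusted p = 0.063 with an estimated correlation). The desaturase SCD fell from 437 ± 17.4 to 95.1 ± 3.69 FPKM and ACSS2, which activates acetate, from 99.4 ± 5.31 to 25.0 ± 1.18 FPKM.

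Most genes of cell division fell. Of 35 tested genes of G2 phase and mitosis 35 fell, also when adjusted over the list alone (median log2 fold change -1.62, camera adjusted p = 7.7e-22). MKI67, the proliferation marker Ki-67, fell from 15.7 ± 3.48 to 2.56 ± 0.228 FPKM and KIF20A, a mitotic kinesin, from 15.3 ± 3.10 to 1.90 ± 0.191 FPKM. Of 42 genes of S phase and DNA replication 1 rose and 31 fell, and 1 and 33 did when adjusted over the list alone (median -0.70, adjusted p = 1.3e-09). UHRF1, which maintains DNA methylation at replication, fell from 4.84 ± 0.565 to 0.837 ± 0.205 FPKM. GINS2, of the replicative helicase, fell 3.38-fold and CLSPN, of the replication checkpoint, fell 6.35-fold. Of 24 p53 targets 5 rose and 3 fell, also when adjusted over the list alone (median 0.10, adjusted p = 0.417). The cell cycle inhibitor CDKN1A rose from 11.9 ± 1.24 to 21.2 ± 0.344 FPKM, and SESN2, BTG2 and BBC3 rose 4.09-fold, 2.28-fold and 2.05-fold. Replication-dependent histones, whose mRNAs mostly lack a poly(A) tail, gave 0 higher and 2 lower of 8, also when adjusted over the list alone (median -0.35, adjusted p = 0.172). HIST1H4C and HIST1H1C fell 2.27-fold and 1.45-fold, with uncertain values because of near-identical copies.

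The Par complex, which sets cell polarity through atypical protein kinase C, had 4 of 6 tested members higher and 0 lower in DON, also when adjusted over the list alone. PRKCZ, an atypical protein kinase C, rose from 14.7 ± 0.845 to 27.0 ± 0.870 FPKM (log2 fold change 0.84 ± 0.08 SE, limma adjusted p = 0.000448). PRKCI, the other such kinase, rose from 18.8 ± 0.931 to 26.2 ± 2.14 FPKM (0.46 ± 0.09, adjusted p = 0.00836). The scaffold PARD3 rose from 23.5 ± 3.40 to 35.6 ± 3.87 FPKM (0.58 ± 0.13, adjusted p = 0.0131), a call lost without DON replicate 2 (adjusted p = 0.0573). PARD6B, an adaptor, rose from 23.2 ± 2.04 to 29.997 ± 2.03 FPKM (0.36 ± 0.10, adjusted p = 0.0259). Its call was lost without vehicle 1, vehicle 2, DON 2 or DON 3, at adjusted p of 0.0804, 0.0840, 0.103 and 0.0887. PARD6A stood at 3.64 ± 0.0953 FPKM in vehicle and 4.98 ± 1.15 FPKM in DON (adjusted p = 0.109), and the GTPase CDC42 at 117 ± 8.47 and 95.1 ± 14.3 FPKM (adjusted p = 0.101). With the GC correction both passed, PARD6A as higher (adjusted p = 0.00599) and CDC42 as lower (adjusted p = 0.0233). Both also passed with the split term, a term for the library split seen in the principal components. Adjusted p was then 0.0342 for PARD6A and 0.00396 for CDC42. PARD6A passed without DON replicate 3 (adjusted p = 0.0390), and CDC42 passed as lower with a replicate block (adjusted p = 0.0268). PARD3B and PARD6G stayed at or below 0.058 FPKM and were not tested. As a list the complex shifted upward (median 0.41, camera adjusted p = 0.0410, and adjusted p = 0.219 with an estimated correlation). The list's call was also lost without vehicle 1 (adjusted p = 0.0706) or DON 1 (adjusted p = 0.0502), and without a filter (0.0664). A filter at 5 FPKM (0.0761), quantile normalization (0.0527), the split term (0.0770) and a replicate block (0.0658) ended it too. Its median was 0.48 within vehicle 1, vehicle 2 and DON 1 and 0.39 within vehicle 3, DON 2 and DON 3.

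**Figure D2:**
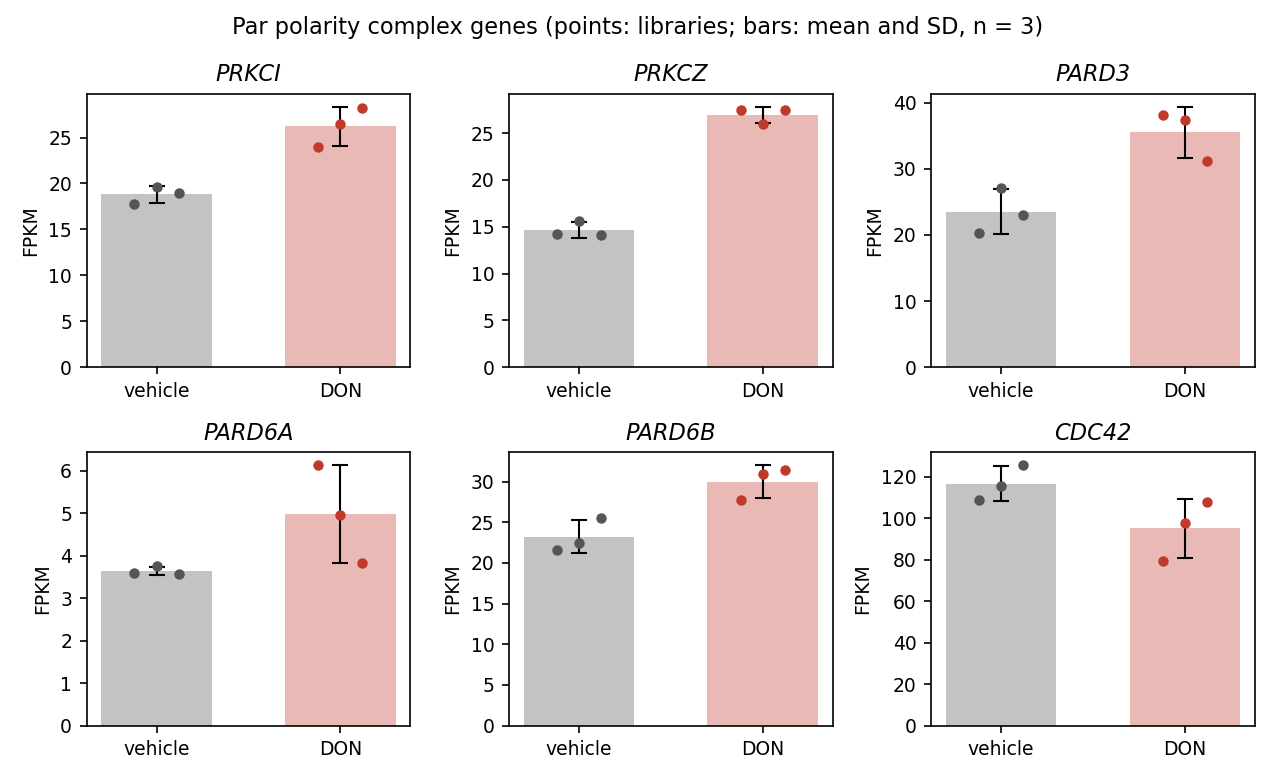
FPKM of the 6 tested Par complex genes in vehicle (grey) and DON (red), with points for libraries, bars for the mean and error bars for the SD (n = 3). PRKCZ lies at 14.7 FPKM in vehicle and 27.0 FPKM in DON on average, and CDC42 at 117 and 95.1 FPKM.

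Other polarity genes and the macropinocytosis machinery had members that moved each way. Of 20 tested Crumbs, Scribble and Par kinase genes 6 rose and 3 fell, also when adjusted over the list alone (median -0.10, mean -0.017, camera adjusted p = 0.933 with an upward direction). The polarity kinases MARK3 and MARK4 rose 1.63-fold and 1.96-fold, and LLGL2, of the Scribble group, fell from 39.2 ± 5.80 to 23.5 ± 3.75 FPKM. With the GC correction the log2 fold change of LLGL2 went from -0.72 to -0.46. That of MARK3 went from 0.67 to 0.60 and that of MARK4 from 0.74 to 0.92, and these calls held. LIN7B, of the Crumbs complex, rose 1.73-fold (adjusted p = 0.0423), a call lost whenever any library other than vehicle 3 was left out, at adjusted p up to 0.1202. Of 42 macropinocytosis genes 8 rose and 6 fell, and 6 and 4 did when adjusted over the list alone (median 0.06, adjusted p = 0.621). The sorting nexin SNX9 rose from 31.9 ± 1.76 to 58.1 ± 4.10 FPKM, the actin regulator WASF2 from 33.6 ± 1.56 to 52.4 ± 2.14 FPKM and the deubiquitinase USP8 from 13.2 ± 0.907 to 19.9 ± 2.11 FPKM. The kinase PAK4 fell from 17.7 ± 1.75 to 12.5 ± 1.21 FPKM (adjusted p = 0.0147), a call lost without vehicle 2 (0.0544) or DON 2 (0.0668).

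EGF receptor signalling genes and EPH receptors rose more often than they fell, with 10 of 18 higher and 3 lower, and 11 and 3 when adjusted over the list alone (median 0.31, adjusted p = 0.040, and adjusted p = 0.382 with an estimated correlation). This list's call was lost without vehicle 1, DON 1, DON 2 or DON 3, at adjusted p up to 0.143. It was likewise lost without a filter (0.177), where the list's median turned to -0.0053. Quantile normalization (0.0585), the split term (0.0732) and a replicate block (0.0713) ended the call too. EGFR, the EGF receptor, rose from 43.8 ± 6.53 to 85.3 ± 2.89 FPKM. Its ligand EREG rose from 7.60 ± 0.848 to 34.9 ± 1.37 FPKM and HBEGF from 5.65 ± 0.447 to 14.5 ± 2.12 FPKM, and AREG went from 0.714 ± 0.228 to 2.38 ± 0.187 FPKM. ERRFI1, a feedback inhibitor of the receptor, rose 2.996-fold to 76.1 ± 6.65 FPKM.

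In energy metabolism, glycolysis genes fell, with 0 of 24 higher and 14 lower, and 1 and 15 when adjusted over the list alone (median -0.47, adjusted p = 0.00037, and adjusted p = 0.199 with an estimated correlation). ENO1, the main enolase, fell from 375 ± 9.87 to 216 ± 2.24 FPKM, and ALDOC, PFKL and PFKFB4 fell 3.69-fold, 2.40-fold and 2.37-fold. Hypoxia response genes outside glycolysis rose, with 8 of 18 higher and 1 lower, and 9 and 1 when adjusted over the list alone (median 0.37, adjusted p = 0.0018, and adjusted p = 0.084 with an estimated correlation). VEGFA, an angiogenic factor also in the ATF4 list, rose from 29.6 ± 2.47 to 59.9 ± 4.95 FPKM, and ANKRD37, ADM and NDRG1 rose 5.94-fold, 3.58-fold and 2.21-fold. Nuclear genes of oxidative phosphorylation gave 2 higher and 7 lower of 34, and 1 and 5 when adjusted over the list alone (median -0.20, adjusted p = 0.040, and adjusted p = 0.382 with an estimated correlation). That call was lost without DON 1 (0.0541) or DON 3 (0.0831). NDUFS8, of complex I, fell from 104 ± 9.504 to 57.9 ± 1.05 FPKM, while SDHA and NDUFA9 fell 1.63-fold and 1.39-fold. UQCRB rose 1.36-fold (adjusted p = 0.0142), a call lost with the GC correction (0.0645) and without DON 2 (0.0661).

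Autophagy genes rose, with 18 of 35 higher and 1 lower, and 19 and 1 when adjusted over the list alone (median 0.35, adjusted p = 2.9e-05). WIPI1, which binds early autophagic membranes, rose from 2.58 ± 0.269 to 15.7 ± 2.23 FPKM and GABARAPL1 from 12.2 ± 1.56 to 40.5 ± 1.10 FPKM. ATG4A and the receptor OPTN rose 2.30-fold and 1.85-fold. Lysosome genes gave 4 higher and 6 lower of 36, and 2 and 6 when adjusted over the list alone (median -0.036, adjusted p = 0.933). The protease CTSL rose from 32.4 ± 1.84 to 62.1 ± 4.71 FPKM, and ATP6V0C, a subunit of the vacuolar proton pump, fell from 215 ± 4.60 to 142 ± 4.44 FPKM, a call lost with the GC correction (adjusted p = 0.0709). In the NRF2 antioxidant list 9 of 25 rose and 2 fell, also when adjusted over the list alone (median 0.22, adjusted p = 0.019, and adjusted p = 0.382 with an estimated correlation), and without vehicle 1 its adjusted p was 0.0713. GCLC, which starts glutathione synthesis, rose from 48.9 ± 1.61 to 145 ± 5.27 FPKM and TXNRD1, a thioredoxin reductase, from 262 ± 9.17 to 596 ± 22.7 FPKM. SRXN1 rose 2.83-fold, and the malic enzyme ME1 fell 2.46-fold.

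Markers of the classical subtype of pancreatic cancer fell, with 1 of 14 higher and 9 lower, and 1 and 11 when adjusted over the list alone (median -0.57, adjusted p = 0.0090, and adjusted p = 0.104 with an estimated correlation). LYZ fell from 250 ± 67.8 to 98.5 ± 19.9 FPKM, and REG4 and TFF3 fell 2.44-fold and 2.30-fold. The member that rose, AGR2, a disulfide isomerase of the endoplasmic reticulum, went from 280 ± 42.0 to 766 ± 92.2 FPKM. CDH17, a further member, stood at 462 to 565 FPKM in DON. It held failure marks in every vehicle library, so no comparison was possible. Basal-like markers gave 1 higher and 5 lower of 12, also when adjusted over the list alone (median -0.29, adjusted p = 0.085), and LEMD1 and TNS4 fell 5.09-fold and 2.14-fold. That list passed without DON 1 (adjusted p = 0.0201), DON 2 (0.0272) or DON 3 (0.0491). Epithelial junction genes gave 3 higher and 10 lower of 28, also when adjusted over the list alone (median -0.074, adjusted p = 0.268). The tight junction genes CLDN3 and CLDN1 fell from 241 ± 44.6 to 105 ± 24.4 FPKM and from 58.1 ± 10.8 to 33.2 ± 4.90 FPKM, and the epithelial splicing factor ESRP1 rose 2.10-fold. Genes of epithelial to mesenchymal transition gave 3 higher and 4 lower of 13, also when adjusted over the list alone (median 0.091, adjusted p = 0.893). SNAI2 rose 2.25-fold, and CTGF and TNC fell 2.68-fold and 2.44-fold. Of 5 tested mucins 0 rose and 2 fell, also when adjusted over the list alone (median -0.010, adjusted p = 0.621). MUC1 fell 2.23-fold (adjusted p = 0.00452, and 0.0531 with the GC correction), and MUC13 fell 1.68-fold (adjusted p = 0.0289), a call lost when vehicle 2, vehicle 3, DON 1 or DON 2 was left out, at adjusted p up to 0.0705.

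Interferon response genes fell, with 3 of 28 higher and 11 lower, and 3 and 12 when adjusted over the list alone (median -0.34, adjusted p = 0.0034, and adjusted p = 0.116 with an estimated correlation). IFIT1 and IFIT2 fell from 9.84 ± 0.672 to 2.43 ± 0.268 FPKM and from 23.9 ± 1.43 to 8.14 ± 0.989 FPKM, and OASL and OAS3 fell 2.52-fold and 2.53-fold. NF-kB and cytokine genes gave 3 higher and 6 lower of 19, and 3 and 7 when adjusted over the list alone (median -0.36, adjusted p = 0.144). The chemokine CXCL5 fell 3.88-fold and NFKBIA, the inhibitor of NF-kB, fell 1.83-fold, while SOD2 rose 1.88-fold. Antigen presentation genes gave 3 higher and 1 lower of 13, and 5 and 2 when adjusted over the list alone (median 0.27, adjusted p = 0.452). TAPBP fell from 61.7 ± 3.62 to 26.9 ± 1.14 FPKM, and ERAP1, TAP1 and HLA-E rose 1.71-fold, 1.43-fold and 1.40-fold. Immediate early genes gave 6 higher and 5 lower of 25, also when adjusted over the list alone (median 0.0012, mean -0.013, adjusted p = 0.933). FOSL2 rose 2.55-fold, and NR4A1 and ETV4 fell 2.77-fold and 2.15-fold.

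Genes of MYC activity and ribosome biogenesis gave 4 higher and 6 lower of 30, also when adjusted over the list alone (median -0.079, adjusted p = 0.739). POLR1A, the largest subunit of RNA polymerase I, fell 2.21-fold, its partner POLR1E rose 1.90-fold, and the nucleolar NOP56 fell from 66.7 ± 3.70 to 40.8 ± 2.74 FPKM. Of 48 cytosolic ribosomal protein genes 2 rose and 2 fell, and 0 and 0 did when adjusted over the list alone (median 0.061, adjusted p = 0.467). RPL7 and RPS25 were called higher and RPS15 and RPS2 lower, and each of these calls was lost with quantile normalization.

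Most markers of other cell types stood near the floor in this cell line. Of 11 fibroblast markers only LUM passed the expression filter, and it went from 153 ± 16.0 to 110 ± 19.2 FPKM (adjusted p = 0.0387), a call lost when any single library was left out, at adjusted p up to 0.0905. Of 14 leukocyte markers only CD68, a lysosomal glycoprotein, passed the filter, at 22.6 ± 5.72 FPKM in vehicle and 32.8 ± 7.19 FPKM in DON (adjusted p = 0.101). With a single tested member, adjustment over the list alone is no adjustment, and the unadjusted p counted CD68 as higher. CD68 passed as higher without vehicle 3 (0.0449) or DON 1 (0.0482), and with a replicate block (0.0287). None of 8 endothelial or 14 acinar and islet markers passed the filter. Of 8 markers of the HEK-293 line only ZIC2 did, at 5.83 ± 0.315 and 4.83 ± 0.0489 FPKM (adjusted p = 0.0799). Its unadjusted p, which is all that adjustment over this list gives, counted ZIC2 as lower. All other members of these lists stayed at or below 1.41 FPKM in every library.

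**Figure D3:**
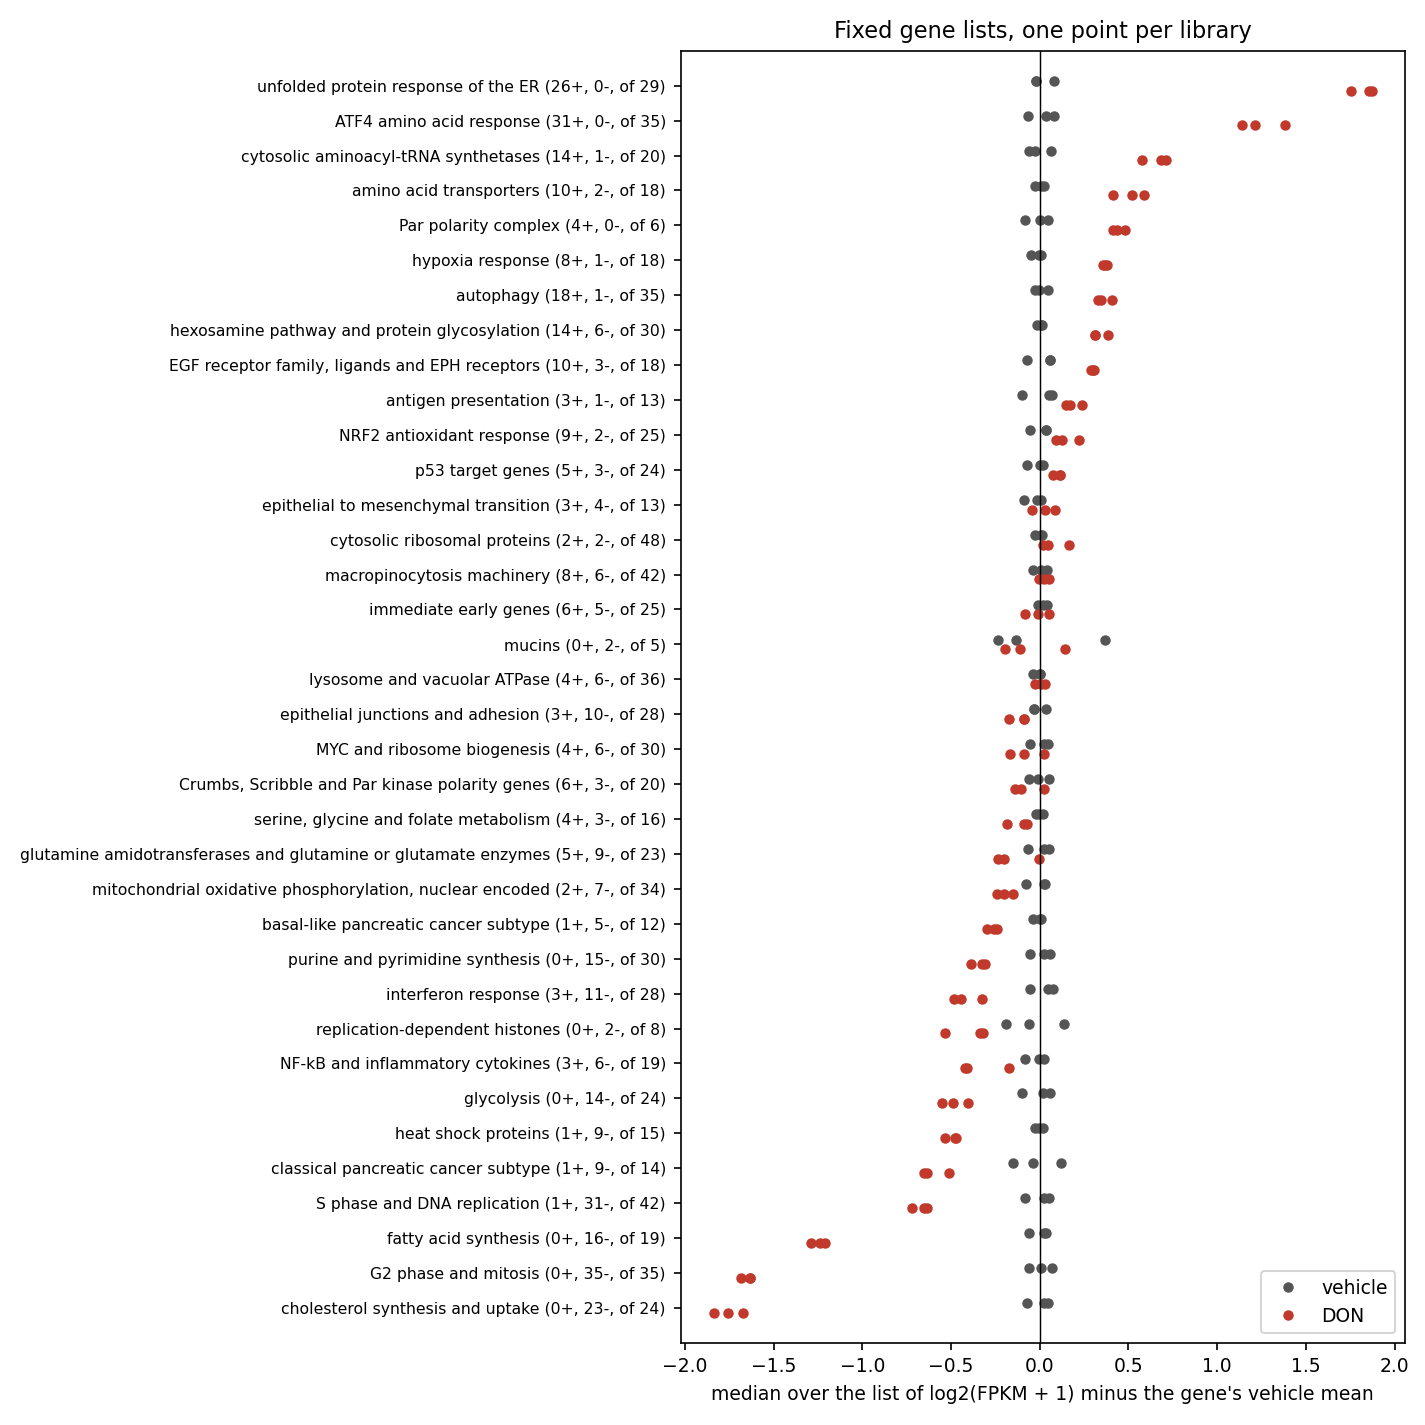
Median of each tested list in each library, as log2(FPKM + 1) minus the gene's mean in vehicle, with 1 point per library (grey vehicle, red DON), and the numbers of members higher and lower among those tested in brackets. DON medians reach from -1.84 for cholesterol synthesis to 1.87 for the unfolded protein response, and those of the macropinocytosis list lie between -0.0039 and 0.052.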

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

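The GC correction, the term for the library split, the fit with failed estimates kept and the fit without small RNA genes were chosen after seeing the data. Of 121 counts recomputed under other settings 117 stayed within 1.5 times, as did the direction and call of 626 of 680 list tests and of 2472 of 2553 values for named genes. Among 146 called named genes 129 kept direction and call in each setting run, 17 lost the call in at least 1, and 0 changed direction. Most named genes were picked for the size of a called change, which favours such stability. Of all 4459 called genes, 2684 kept direction and call without DON replicate 2 and 3955 without DON replicate 1, with the other left-out libraries between. Leaving out 1 library gave 2688 to 4639 changed genes, 1184 to 2105 higher and 1504 to 2534 lower, with the lowest values without DON replicate 2. Fewer samples raise the error, and the likeness of the libraries left also differed. Without DON 2 the DON libraries left were DON 1 and DON 3, the least alike of that group (Pearson correlation 0.971). Without DON 1 they were DON 2 and DON 3, the most alike (0.990), and 4639 genes were called. The counts thus went with the spread of the DON libraries left, though this was not tested separately. Camera with an estimated correlation called 6 lists in place of 20. Both runs allow for correlation between members, at a preset or an estimated size, and the cause of the drop was not tested.

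The Par complex list lost its call without a filter (0.0664) and with a filter at 5 FPKM (0.0761), which removes PARD6A. The same held with quantile normalization (0.0527), with the split term (0.0770) and with an estimated correlation (0.219). The adjusted p of this list ranged from 0.0377 to 0.0706 when 1 library was left out, and the cause was not tested. With a replicate block it was 0.0658, that of the EGF receptor list was 0.0713, and CDC42 was called lower (0.0268). The paired fit called 5414 genes, 2551 higher and 2863 lower, 824 at least 2-fold changed, and 18 lists. The numbers need not pair the libraries: deviations of same-numbered libraries correlated by 0.25, -0.18 and 0.50 across genes, and not every library correlated best with its own number.

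The sign of some list tests that camera had not called turned under other settings, and the cause was not tested. For Crumbs and Scribble genes this was so with a filter at 5 FPKM (adjusted p = 0.669), the replicate block (0.826), the split term (0.912), and without vehicle 3 (0.878) or DON 1 (0.801), in a range of 0.801 to 0.919 over left-out libraries. For lysosome genes it was so with median-of-ratios scaling (0.990), the GC correction (0.770), and without DON 2 (0.958), in a range of 0.874 to 0.958 over left-out libraries. For immediate early genes it was so without a filter (0.946) and without vehicle 2 (0.933), in a range of 0.850 to 0.950 over them. The serine list turned upward without a filter (0.954) and the ribosomal protein list downward with quantile normalization (0.887). Fry asks another question, whether members move one way on balance, without comparing them with other genes. Its direction differed from camera's for the serine list (upward, 0.00279), the glutamine enzyme list (upward, 0.0423) and immediate early genes (downward, 0.114). The median of the EGF receptor list became -0.0053 without a filter. The log2 fold change of PPAT, which passed no threshold, was -0.15 with the GC correction and -0.026 to 0.047 with 1 library left out. Absolute depth is unknown, so no detection limit is given for genes near the floor.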

Other observations

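The tests of GC content, of the library split and of regrouped libraries were chosen after the results they bear on had been seen. The genes in this paragraph and the next were chosen after their values were seen. They belong to no tested list. IGFBP1, a secreted binder of insulin-like growth factors, rose from 894 ± 92.3 to 4287 ± 362 FPKM (n = 3 per group). HAS3, a hyaluronan synthase, rose from 6.82 ± 1.96 to 36.8 ± 6.13 FPKM, the hormone gene GAST from 6.01 ± 0.797 to 30.4 ± 1.90 FPKM and LAMB3, a laminin chain, from 57.5 ± 11.6 to 202 ± 37.2 FPKM. GAS6, a ligand of TAM receptor kinases, fell from 22.8 ± 4.33 to 3.74 ± 0.747 FPKM and the matrix protein THBS2 from 41.9 ± 1.13 to 8.74 ± 0.181 FPKM. LGR5 and LGR6, receptors for R-spondins, fell 4.34-fold and 3.35-fold, and the ductal transcription factor SOX9 fell from 30.6 ± 2.21 to 7.32 ± 0.776 FPKM. Each passed limma's test, with adjusted p from 1.61e-05 for THBS2 to 0.000515 for LAMB3.

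Of noncoding hosts of small nucleolar RNAs, 3 picked for their values rose. SNHG1 went from 59.2 ± 6.81 to 280 ± 61.8 FPKM, SNHG12 from 17.2 ± 5.0004 to 87.2 ± 12.04 FPKM and ZFAS1 from 346 ± 12.1 to 888 ± 57.2 FPKM (limma adjusted p of 0.000215, 0.000298 and 9.97e-05). No list of such genes was tested. The keratin KRT8 had failure marks in vehicle 3, DON 2 and DON 3, and stood at 3238 and 3087 FPKM in the vehicle libraries left and at 1294 FPKM in DON 1.

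The breadth of the change was weighed against technical sources. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real split, gave as many genes, with 4459 changed and 802 at least 2-fold changed against at most 2 and 2 in any other split, but 10 splits cannot give a share under 0.05. Fold change itself followed GC content, with a Spearman correlation across genes of -0.261, and of -0.012 once the GC trend of each library was removed. Sizes of single genes moved both ways, as for CLDN3 (log2 fold change -1.19 before and -0.81 after) and PRKCZ (0.84 before and 1.02 after). With that trend removed, 89.4% of the 4459 called genes and 99.6% of the 802 kept direction and call. At least 2-fold falls then numbered 400 in place of 477, and such rises 335 in place of 325. These values argue against GC content as the whole cause. The fold changes of the disjoint sets of libraries that the second principal component parts correlated by 0.809 across genes, which argues against that split as the cause. For list shifts, 1 of 10 splits gave as many as 20 lists and the highest other gave 14, again too few splits for a share under 0.05. Every other split puts DON and vehicle libraries in the same group. Part of the DON effect then lies between its groups, and the rest widens the spread within them, which lowers its gene count. Such a count is not one under no change, so the comparison of splits cannot weigh technical sources.

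The rise of the Par complex was weighed in the same way. A test named before its result was seen asked whether genes of that expression level rose as much in general. Of 10000 random lists matched on mean expression, 3.45% had as high a median, counted on the upper side only. The random lists drew genes independently, so this share allows for no correlation between members and cannot decide the question. All 4 members called higher stayed so with the GC correction, which argues against GC content. Of the 10 splits 1 gave a camera p as small, at 0.0228 against 0.0335 in the nearest other, and 5 of 10 gave a p as small for macropinocytosis genes, at 0.5005 against 0.0639. These splits are too few for a share under 0.05, and here too the others mix DON and vehicle libraries within a group. They cannot weigh the rise. A rise of polarity complex transcripts under blocked glutamine use remains a hypothesis from these data, since the list test itself misses the threshold with an estimated correlation (0.219).

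A candidate explanation for the fall of sterol synthesis genes is an excess of sterols in the cells, which would also raise targets of the LXR receptors, a test named before its result was seen. The 5 tested LXR targets had a median log2 fold change of -0.034. Of these ABCG1 and SMPDL3A rose by 1.31 and 0.83, while MYLIP, LPCAT3 and NR1H3 passed no threshold (-0.03, -0.40 and -0.27), so targets that part in this way leave the question open. GC content is argued against, since the median of the cholesterol list was -1.63 after the correction and -1.68 before it.

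A further hypothesis, also named before its test was run, is that the rise of CYP1A1 and of CYP1B1, which went from 1.54 ± 0.520 to 12.7 ± 0.967 FPKM, may reflect activity of the aryl hydrocarbon receptor. The other 5 tested targets of that receptor had a median log2 fold change of 0.81, which is the value of NFE2L2 itself. Of matched random lists, again of genes drawn independently, 0.3% were as high, so this share rests on NFE2L2. AHRR, the receptor's repressor, rose by 1.59, TIPARP by 1.51 and NFE2L2 by 0.81, whereas ALDH3A1 fell by 1.35 and NQO1 passed no threshold (0.12). NFE2L2 and NQO1 also belong to the NRF2 pathway and to its list tested above, so their values may not have been unseen. That part of the list does not speak for the receptor alone. The remaining targets parted, AHRR and TIPARP upward and ALDH3A1 downward, so the values leave the hypothesis open.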
